A study of Homo sapiens with 4 samples.

How the data were processed

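RNA from U87MG cells, an established human glioblastoma line, was measured on 4 human PrimeView arrays (Affymetrix, 1-colour, biotin label). Per the labels' protocols, the cells were kept at 0.2% oxygen, were transfected with either an empty control vector or a vector that expresses the neurogenic transcription factor NeuroD2, and were harvested 48 hours later. The labels put 2 arrays in each group and call them biological replicates 1 and 2. They do not say how the cultures were separated, so p-values of single genes measure the spread between these samples.

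The only values used were the authors' deposited table of 49395 probe sets, which was taken to be on a log2 scale. That reading rests on the values, which run from 2.65 to 14.3 with medians between 5.98 and 5.99 on the 4 arrays, and on the usual output for this array type. The near-equal medians are those of values normalized between arrays before deposit, but this too is read from the values. The software, background correction, normalization and summary method are not given in the sources used here. Scan dates and detection calls were not used here, so no array batch was tested and no gene was called absent. The scale was not centred per gene, and differences run from control vector to NeuroD2 vector. No sequencing depth applies. The number of arrays limits the precision.

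Genes were named through the platform annotation. Of the probe sets, 44988 carried 1 gene symbol, 1832 carried several, 2473 carried none and 102 were Affymetrix controls. Entrez identifiers of 44961 probe sets were found in the RefSeq gene table of GRCh38.p14, and 0 symbols changed. Only probe sets with 1 symbol were used, giving 18132 genes, of which 11734 had more than 1 probe set. A gene was represented by its probe set with the highest mean over the 4 arrays.

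Groups were compared with limma 3.58.1 (lmFit and eBayes, no intensity trend, group as the only term, two-sided) in R 4.3.3, on 2 residual degrees of freedom and 3.84 prior degrees of freedom. Adjusted p-values are Benjamini-Hochberg values over all genes, with a threshold of 0.05. A size rule, given as a description without error control, counted genes with an absolute log2 difference of at least 1, groups that did not overlap and an unadjusted p below 0.05. An exact permutation test of 2 arrays against 2 cannot go below a two-sided p of 0.333, so none was used for single genes. Gene lists (44, each with at least 8 measured members) were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera at this setting compares a list's genes with all other genes. Its p-values therefore measure the spread between genes and not the spread between cultures. Each list's members were also adjusted over the list alone. The median of a list was set against 10000 random lists matched on mean level in 20 bins.

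The groups, the test, the lists, the rule for named genes and the alternatives were fixed before the data were examined. The rule named NEUROD2, the 12 largest rises and 12 largest falls among genes past the adjusted threshold, and up to 4 members of each described list with the largest absolute difference. Members named outside this rule are said to be chosen afterwards. The alternatives were the replicate number as a block, leaving out each array in turn, quantile normalization, centring on array medians, an intensity trend, a robust prior, a filter on dim genes, the mean of a gene's probe sets, every probe set tested on its own, and for lists an estimated correlation and fry, which asks whether a list's genes move on balance in 1 direction without comparing them with other genes.

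The fits were tested on simulated data with the real gene means and with variances drawn from limma's fitted prior, which favours limma, in 20 draws of 18132 genes with 100 genes changed at each size. For 2 NeuroD2 arrays against 2 control arrays, 88.0% of genes changed by 1 on the log2 scale were recovered. Of those changed by 0.5, 8.55% were recovered, and 4.69% of all calls were false. The real data gave 864 calls, more than the 100 changed genes simulated at each size. Recovery depends on the share of changed genes, so these rates need not hold for the real data. Both simulated groups had the same spread. In a simulated comparison of 44 lists with independent genes, camera called a list shifted by 0.3 with the preset correlation (adjusted p = 1.25e-33). It did not with an estimated correlation (adjusted p = 0.204), and 0 unshifted lists were called with the preset correlation. As the simulated genes were independent, that 0 does not show how often lists of correlated genes are falsely called.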

Results

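The data consisted of 4 expression profiles of U87MG glioblastoma cells grown at 0.2% oxygen, 2 from cells that received the control vector and 2 from cells that received the NeuroD2 vector, all harvested 48 hours after transfection. The design addresses which transcripts change when NeuroD2, a basic helix-loop-helix factor of neuronal differentiation, is overexpressed in hypoxic glioblastoma cells. Across the 18132 genes, which are not independent replicates, the 2 control arrays correlated at r = 0.998 and the 2 NeuroD2 arrays at r = 0.999, while each pair from different groups correlated at 0.995. The median absolute difference was 0.12 log2 units between the control arrays and 0.07 between the NeuroD2 arrays.

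NEUROD2 itself rose on the brightest of its 3 probe sets, from 5.40 ± 0.08 to 7.60 ± 0.32 (log2, SD, n = 2 each). The difference was 2.19 with a 95% interval of 1.82 to 2.57, which is 4.58-fold, at an adjusted p of 0.0044 by limma. On the other 2 probe sets, fitted among all probe sets, the differences were -0.21 on the second-brightest (adjusted p = 0.511) and -0.07 on the dimmest (adjusted p = 0.682), with levels between 4.42 and 4.90 on every array. The mean of the 3 probe sets gave a smaller difference of 0.64 (adjusted p = 0.013). Without control replicate 1 the adjusted p was 0.141 and without control replicate 2 it was 0.147, the highest over all alternatives, of which the lowest was 0.00014. Among relatives measured on 6 probe sets (NEUROD4, NEUROD6, NEUROG1, NEUROG2 and NEUROG3), differences ran from -0.11 to 0.02 and the lowest adjusted p was 0.569.

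The spiked-in control RNAs differed between arrays. All 18 hybridisation spike probe sets were brighter on both NeuroD2 arrays than on both control arrays, by 0.39 on average (9.73 ± 0.24 against 10.12 ± 0.02, SD, n = 2 each). They averaged 9.56 and 9.90 on control replicates 1 and 2 and 10.10 and 10.13 on the NeuroD2 arrays, so the difference was 0.22 without control replicate 1 and 0.56 without control replicate 2. The poly-A spikes, which are carried through the labelling, averaged 6.95 on control replicate 1 and between 7.96 and 8.03 on the other 3 arrays. All 24 of their probe sets were lowest on control replicate 1. The 18S rRNA 3' probe set was also lowest there, at 11.33 against 12.09 to 12.14 on the other 3 arrays. Background probe sets averaged 2.87 on the control arrays and 2.90 on the NeuroD2 arrays at low GC content, and 7.62 and 7.87 at high GC content. At high GC content single arrays ran from 7.46 to 7.95. The difference of 0.25 there was 0.42 without control replicate 1 and 0.08 without control replicate 2. No gene's level was set against background of matching GC content. The 3' minus 5' difference lay between -0.12 and -0.08 for GAPDH and between 0.07 and 0.14 for ACTB.

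**Figure D1:**
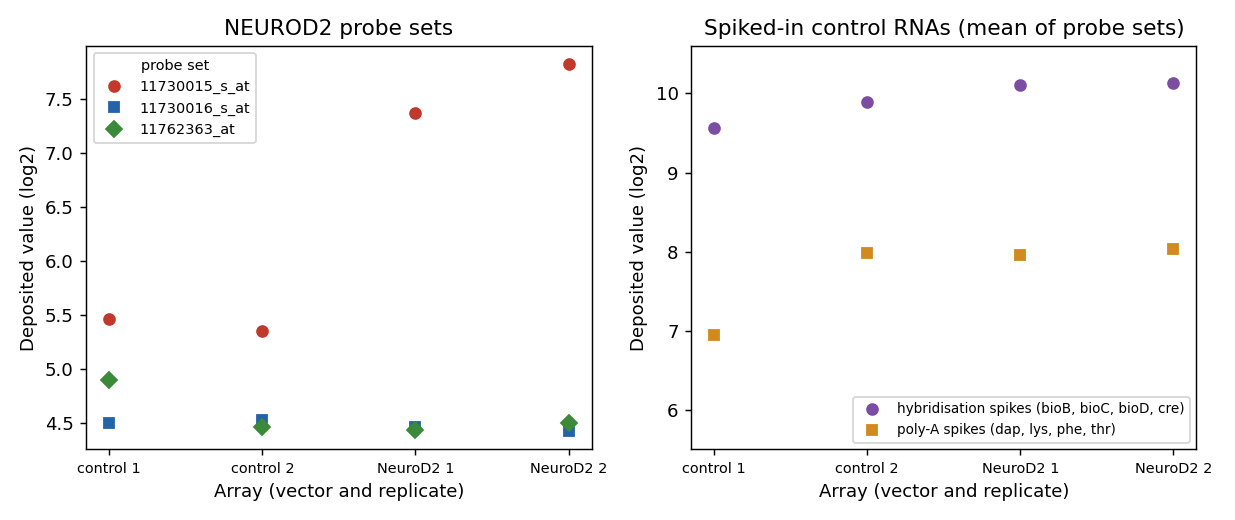
Left, deposited log2 values of the 3 NEUROD2 probe sets on each of the 4 arrays (1 point per array). Right, mean log2 value of 18 hybridisation spike and 24 poly-A spike probe sets on each array, with the axis starting above 0. Of the 3 NEUROD2 probe sets, the brightest was higher with the NeuroD2 vector, and the poly-A spikes of control replicate 1 averaged 6.95.

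With the NeuroD2 vector, the largest rises included genes of secreted inflammatory mediators and the metalloproteinase genes MMP1 and MMP3. IL24, a cytokine of the interleukin-10 family, showed the largest rise, 14.5-fold, from 5.69 ± 0.33 to 9.55 ± 0.01 (log2, SD, n = 2 each; difference 3.86, standard error 0.15, adjusted p = 0.00092). With the mean of its probe sets the rise was 2.92, or 7.56-fold, below the 3.03 of PTGS2. PTGS2, the inducible enzyme of prostaglandin synthesis, rose 7.79-fold from 8.84 ± 0.12 to 11.80 ± 0.09. The collagenase gene MMP1 rose 5.38-fold and the stromelysin gene MMP3 5.27-fold, and the growth factor gene BMP2 rose 5.24-fold. The neutrophil chemokine gene CXCL5 rose 5.20-fold, and IL1B, which encodes interleukin-1 beta, rose 5.15-fold to a level of 13.69 ± 0.03. Further rises were measured for CSF3, the granulocyte colony-stimulating factor (3.76-fold), the tight-junction gene CLDN14 (3.44-fold), the interleukin-36 receptor antagonist gene IL36RN (3.36-fold) and the protease inhibitor gene SERPINB4 (3.11-fold). Adjusted p-values of these genes in limma lay between 0.00065 and 0.0050. SERPINB4 has a close paralog, SERPINB3, and its probe set can read both; on its own probe set SERPINB3, examined afterwards, differed by 0.50 (adjusted p = 0.0897).

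The largest falls were in genes of varied function. GALNT10, an enzyme that starts O-linked glycosylation, fell by 1.66 on the log2 scale, from 8.21 ± 0.08 to 6.55 ± 0.15 (SD, n = 2 each; adjusted p = 0.0033 by limma). CCL2, the monocyte chemokine, fell by 1.64, from 8.84 ± 0.04 to 7.20 ± 0.01. Further falls were measured for FAM13C (-1.60), TMT1A (-1.49), the cyclic GMP phosphodiesterase gene PDE5A (-1.47) and the anion exchanger gene SLC26A4 (-1.41). The adhesion gene AMIGO2 (-1.33), the formyl peptide receptor gene FPR1 (-1.31), the complement regulator gene CFI (-1.30), IFITM10 (-1.29) and the sialyltransferase gene ST8SIA5 (-1.28) fell as well. MAP2, a neuronal microtubule-associated protein, fell by 1.23, from 5.81 ± 0.29 to 4.58 ± 0.02. Adjusted p-values of these genes lay between 0.0013 and 0.0146. With the mean of each gene's probe sets the differences were smaller for FAM13C (-0.95), TMT1A (-0.73), PDE5A (-0.95) and FPR1 (-0.76).

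**Figure D2:**
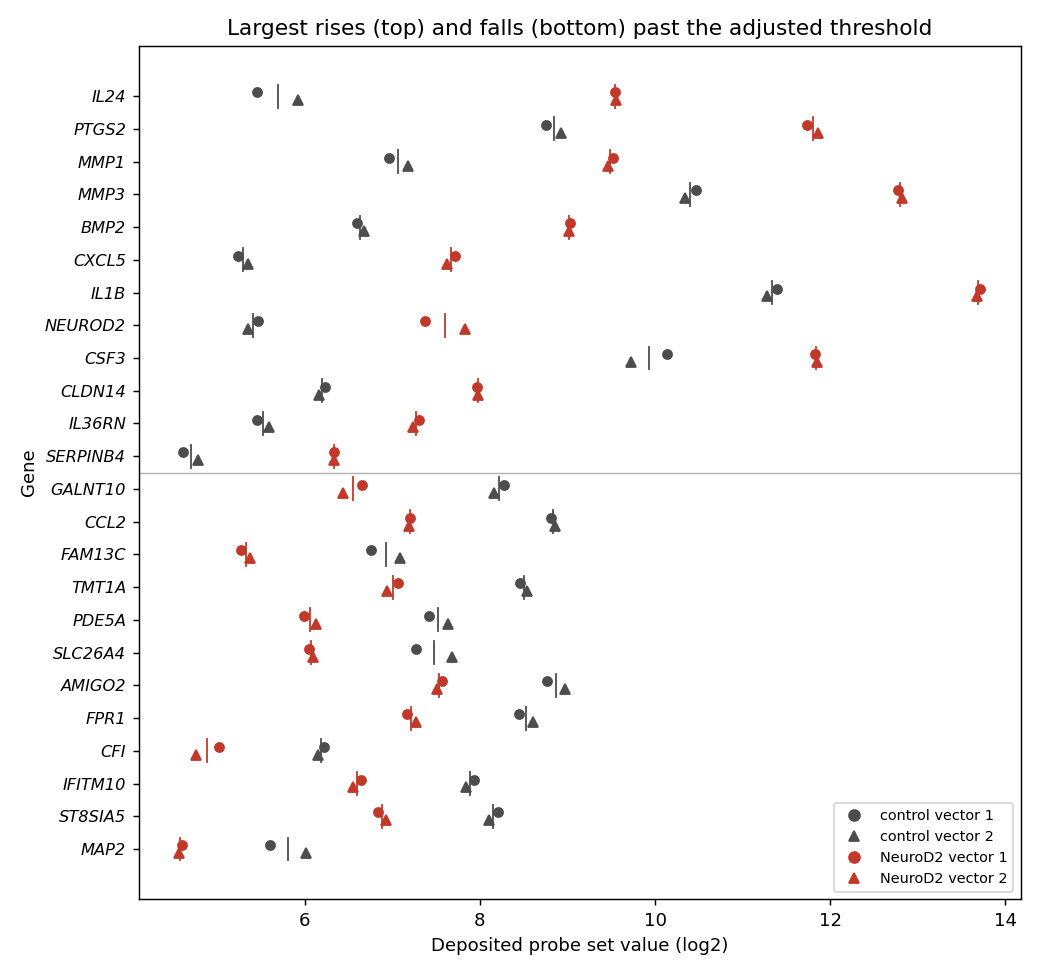
Deposited log2 value (x axis) of the 12 genes with the largest rise and the 12 with the largest fall among genes past the adjusted threshold, 1 point per array, with a bar at each group's mean (n = 2). In each gene both NeuroD2 arrays lie on the same side of both control arrays, and the differences run from 3.86 for IL24 to -1.23 for MAP2.

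In all, 864 of the 18132 genes passed an adjusted p of 0.05 by limma, 328 higher and 536 lower with the NeuroD2 vector, and 3946 had an unadjusted p below 0.05. The median absolute difference of the changed genes was 0.55 on the log2 scale. The size rule was met by 78 genes, 42 higher and 36 lower, all of which also passed the adjusted test. The groups did not overlap in 50.8% of genes, against 33.3% expected by chance for 2 arrays against 2. Among the 24 named genes, 17 had more than 1 probe set. In 15 of these every probe set moved the same way, the exceptions being NEUROD2 and AMIGO2. Of the 24, 10 were read on probe sets with the suffix s_at or x_at, kinds that can match transcripts of more than 1 gene. The count rested on all 4 arrays: by limma it was 0 without control replicate 1 (4428 genes at an unadjusted p below 0.05), 0 without control replicate 2 (4102), 57 without NeuroD2 replicate 1 and 66 without NeuroD2 replicate 2. Of the 24 named genes, which were picked on all 4 arrays, 22 passed without either NeuroD2 array, the exceptions being SLC26A4 and MAP2. Without either control array, the single remaining control was assumed to vary like the NeuroD2 arrays, and the smallest adjusted p was 0.141 without control replicate 1 and 0.133 without control replicate 2.

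Of the 44 gene lists, 12 shifted as a whole by camera with the preset correlation, 3 upward and 9 downward. None of these passed with an estimated correlation. That setting rests on the 2 residual degrees of freedom and also missed the list shifted by 0.3 in the simulation. Not passing it therefore does not show that a shift is absent. For inflammatory NF-kB targets (-0.02), immediate early genes (0.001), interferon response (-0.002), DNA repair (-0.02) and fatty acid synthesis (-0.07) the estimated correlation lay below the preset 0.01. It lay above for cholesterol synthesis (0.13), extracellular matrix (0.09), oxidative phosphorylation (0.08), hypoxia targets (0.03), histone (0.03), G1/S (0.03) and G2/M genes (0.011). Where the preset lies below the true correlation, camera p-values are too small. Against random lists matched on mean level, the medians of the 3 upward lists stood at percentile 100 and those of the 9 downward lists between 0 and 2.79. Of the lists that did not pass, synaptic genes stood at 2.20, angiogenesis factors at 99.9 and the other 30 between 6.57 and 95.4. Inflammatory NF-kB target genes shifted most. Of 29 measured members, 16 rose, 2 fell and 11 did not pass, and 18 rose and 2 fell when adjusted over the list alone. The median difference was 0.54 (camera adjusted p = 7.56e-15; adjusted p = 0.359 with an estimated correlation). PTGS2, CXCL5, IL1B and CSF3 had the largest differences. The 2 members that fell, named after their values were seen, were the chemokine gene CCL2 (-1.64) and TNFAIP2 (-0.92). Among 32 immediate early genes, 6 rose, 1 fell and 25 did not pass, with 11 higher and 1 lower when adjusted over the list alone (median 0.19, camera adjusted p = 1.03e-06; adjusted p = 0.380 with an estimated correlation). IER3 (0.88), the transcription factor gene EGR1 (0.88, and 0.56 with the mean of its probe sets) and the MAP kinase phosphatase gene DUSP6 (0.83) rose, while KLF4 fell by 1.04. On the same arrays the hybridisation spikes read 0.39 higher with the NeuroD2 vector, and 0.22 higher without control replicate 1. The median of the NF-kB list was 0.94 when only genes at or above the median level were kept.

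Cell cycle genes were lower with the NeuroD2 vector. Of 33 G2/M genes, 9 fell and 24 did not pass, and 27 fell when adjusted over the list alone (median -0.36, camera adjusted p = 8.68e-14; adjusted p = 0.359 with an estimated correlation). The genes of the kinesin KIF20A (-0.65), cyclin A2 (CCNA2, -0.57) and the spindle checkpoint kinase TTK (-0.47) fell, as did that of the mitotic phosphatase CDC25B (-0.68), which did not pass with the mean of its probe sets (-0.34, adjusted p = 0.087). Of 32 G1/S genes, 3 fell and 29 did not pass, and 19 fell and 1 rose when adjusted over the list alone (median -0.25, camera adjusted p = 9.20e-09; adjusted p = 0.380 with an estimated correlation). The replication genes GINS1 (-0.49) and PCNA (-0.43) fell, PCNA not passing with the mean of its probe sets (-0.26, adjusted p = 0.074), and E2F2 (-0.48, and -0.32 without control replicate 1) and TK1 (-0.41) did not pass. Of 26 DNA repair genes 1 fell, PARP1 (-0.54), and 25 did not pass, with the same count over the list alone (median -0.13, camera adjusted p = 0.0088; adjusted p = 0.468 with an estimated correlation). That shift did not pass without control replicate 2 (adjusted p = 0.112), with a range of 0.001 to 0.468 over all alternatives. Histone genes shifted upward (median 0.14, camera adjusted p = 0.0059; adjusted p = 0.514 with an estimated correlation), with 2 of 27 higher, 2 lower and 23 not passing, and 8 higher and 2 lower over the list alone. H3C4 rose by 0.56 and the variant histone gene MACROH2A1 fell (-0.44), while H2BC4 (0.48, and 0.28 without control replicate 1) and H4C8 (0.44) did not pass. Histone genes are near-identical copies whose signals can be shared, and the shift did not pass among genes at or above the median level (median 0.08, adjusted p = 0.218) or with fry (adjusted p = 0.057), with a range of 0.0039 to 0.514 over all alternatives. With the replicate number as a block, CCNA2, TTK, GINS1, PCNA, PARP1 and MACROH2A1 did not pass (adjusted p from 0.0503 to 0.0762). The hybridisation spikes read 0.39 higher on the NeuroD2 arrays (0.22 without control replicate 1).

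Lipid synthesis genes were lower as well. Of 19 cholesterol synthesis genes, 6 fell and 13 did not pass, and 10 fell when adjusted over the list alone (median -0.36, camera adjusted p = 7.06e-08; adjusted p = 0.468 with an estimated correlation). HMGCS1, an early enzyme of the mevalonate pathway, fell by 1.17, and IDI1 (-0.57), EBP (-0.53) and DHCR7 (-0.52), which act later in the pathway, fell too. Of 15 fatty acid synthesis genes, 3 fell and 12 did not pass, and 4 fell over the list alone (median -0.12, camera adjusted p = 0.0137; adjusted p = 0.489 with an estimated correlation). The desaturase genes FADS2 (-0.75) and SCD (-0.53, and -0.87 with the mean of its probe sets) and the carboxylase gene ACACB (-0.64) fell, while SREBF1, a transcriptional regulator of lipid synthesis, did not pass (-0.40). ACACB did not pass with the mean of its probe sets (-0.25, adjusted p = 0.104). The fatty acid shift did not pass without control replicate 2 (median -0.06, adjusted p = 0.109) or among genes at or above the median level (adjusted p = 0.218), and its median was -0.07 without NeuroD2 replicate 2 (adjusted p = 0.031, with a range of 0.006 to 0.489 over all alternatives). With the replicate block, IDI1, EBP, DHCR7 and SCD did not pass (adjusted p from 0.0515 to 0.0616). Over all alternatives the median of the fatty acid list ran from -0.18 to -0.06. It stood at percentile 2.79 of random lists matched on mean level, inside the central 95% of these lists. The spikes of the hybridisation mix were 0.39 higher on the NeuroD2 arrays here too, and 0.22 higher without control replicate 1.

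Interferon response genes, extracellular matrix genes, hypoxia targets and respiratory chain genes shifted downward by less than the G2/M, G1/S and cholesterol lists. Of 45 interferon response genes, 7 fell and 38 did not pass, and 11 fell over the list alone (median -0.11, camera adjusted p = 0.0022; adjusted p = 0.446 with an estimated correlation). The antiviral genes IFIT1 (-0.91), OAS1 (-0.79), IFIT2 (-0.62) and MX2 (-0.60) fell, MX2 not passing with the mean of its probe sets (-0.30, adjusted p = 0.056) and IFIT2 not with the replicate block (adjusted p = 0.0594). Of 39 extracellular matrix genes, 11 fell, 1 rose and 27 did not pass, and 15 fell and 2 rose over the list alone (median -0.11, camera adjusted p = 0.0022; adjusted p = 0.531 with an estimated correlation). LUM, which encodes the proteoglycan lumican, fell by 1.19, as did the fibrillar collagen genes COL5A1 (-0.83) and COL5A2 (-0.71, and -0.43 with the mean of its probe sets) and the basement membrane gene NID2 (-0.80). The tenascin gene TNC, named after its value was seen, rose by 0.45. The matrix shift did not pass without control replicate 1 (median -0.04, adjusted p = 0.062), and its median was -0.24 without control replicate 2 and -0.02 without NeuroD2 replicate 1, with adjusted p-values from 0.00047 to 0.531 over all alternatives.

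Of 38 hypoxia (HIF) targets, 2 rose, 3 fell and 33 did not pass, and 4 rose and 9 fell over the list alone (median -0.13, camera adjusted p = 0.025; adjusted p = 0.531 with an estimated correlation). The glycolysis regulator gene PFKFB4 fell by 0.59, while the nuclear receptor gene RORA and the glycoprotein hormone gene STC1 rose by 0.55 and 0.51, neither passing with the replicate block (adjusted p = 0.0688 and 0.0616), and ERO1A did not pass (-0.48). The hypoxia shift did not pass without control replicate 2 (adjusted p = 0.156), without NeuroD2 replicate 1 (adjusted p = 0.083), among genes at or above the median level (adjusted p = 0.152) or with the mean of probe sets (adjusted p = 0.094), with a range of 0.011 to 0.531 over all alternatives. Of 52 oxidative phosphorylation genes, 0 passed limma's test over all genes and 0 when adjusted over the list alone, and 5 had an unadjusted p below 0.05, all lower (median -0.10, camera adjusted p = 0.0011; adjusted p = 0.531 with an estimated correlation; fry adjusted p = 0.097). SDHA (-0.27), NDUFB6 (-0.22), NDUFS7 (-0.22) and COX7A2 (-0.21) had the largest differences. With the mean of probe sets NDUFS7 and COX7A2 both differed by -0.12, and NDUFS7 by -0.13 without control replicate 1. The hybridisation spikes differed by 0.39 between the groups on the same arrays, and by 0.22 without control replicate 1.

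Neuronal gene lists did not shift as wholes by camera. Of 34 neuronal markers, 2 rose, 2 fell and 30 did not pass, with the same counts over the list alone (median 0.04, mean -0.02, camera adjusted p = 0.871). The secretory granule genes CHGB and SCG5 rose by 0.43 and 0.39, while MAP2 (-1.23) and DPYSL3 (-0.47) fell. CHGB was dim, at 4.09 on the control and 4.52 on the NeuroD2 arrays, as was the axon guidance gene EPHA5 (4.33 and 3.81). The first quartile of all probe sets was 4.10 and 4.13. CHGB did not pass after quantile normalization (adjusted p = 0.056) or with the mean of its probe sets (0.12, adjusted p = 0.388). With the replicate block CHGB (adjusted p = 0.0762), SCG5 (0.0818), DPYSL3 (0.0635), ATOH8 (0.0604) and EPHA5 (0.0540) did not pass. Of 33 proneural helix-loop-helix cascade genes, 5 fell and 28 did not pass, with the same counts over the list alone (median 0.01, mean -0.07, camera adjusted p = 0.871). ID3, ID2 and ID1, which encode inhibitors of helix-loop-helix factors, fell (-1.21, -0.97 and -0.75), as did ATOH8 (-0.64) and HES6 (-0.44), the last named after its value was seen. Of 40 synaptic genes, PCLO rose by 0.78, SNAP25 fell by 0.59 and 38 did not pass. Over the list alone 2 rose and 1 fell (median -0.05, at percentile 2.20 of matched random lists, camera adjusted p = 0.871). The sign of this median depended on 1 array, with 0.02 without control replicate 1 and -0.07 without control replicate 2. SYT1 (-0.45, -0.26 without NeuroD2 replicate 2 and -0.18 with the mean of its probe sets) and RAB3B (0.37) did not pass. Of 26 voltage-gated ion channel genes the calcium channel gene CACNA1A rose by 0.65 and 25 did not pass, with the same count over the list alone (median 0.03, camera adjusted p = 0.444). Of 40 axon guidance genes 1 fell, EPHA5 (-0.52; -0.24 and adjusted p = 0.115 with the mean of its probe sets), and 39 did not pass, and 2 rose and 2 fell over the list alone (median 0.02, camera adjusted p = 0.671).

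**Figure D3:**
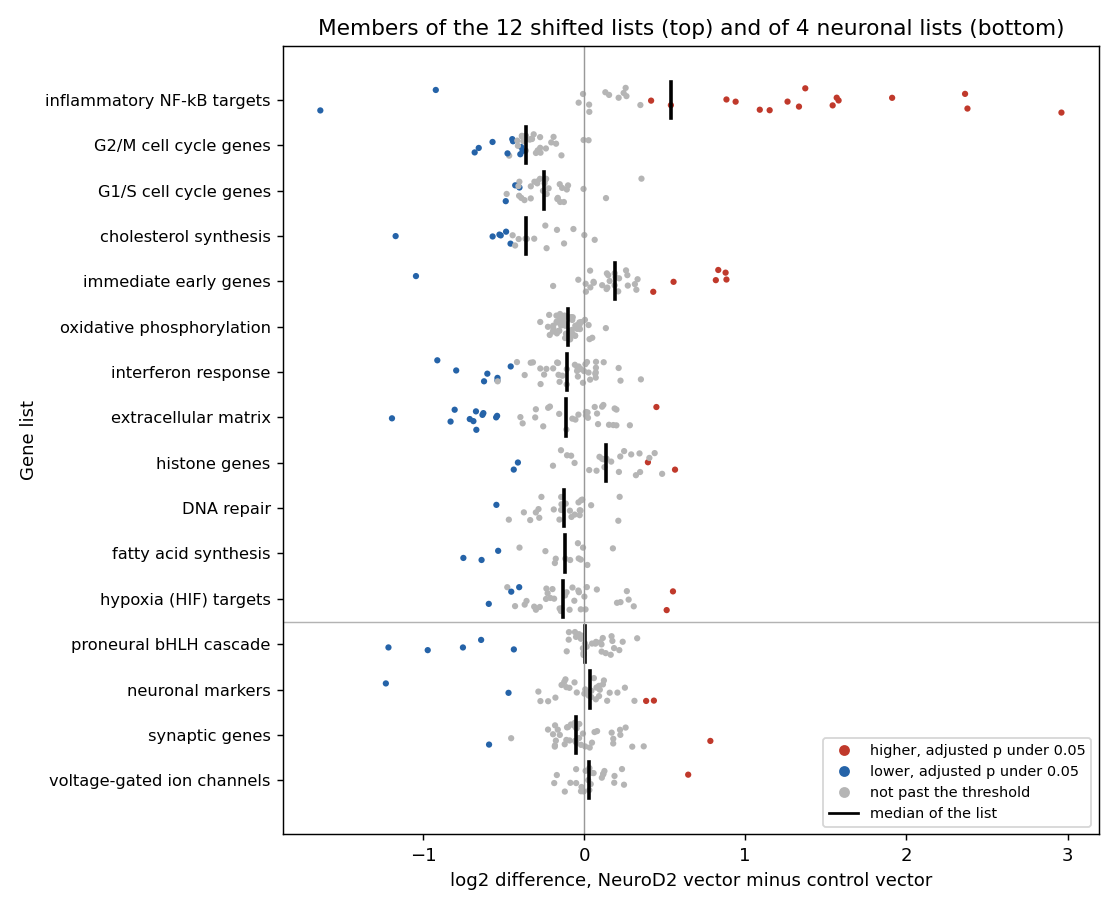
log2 difference (NeuroD2 vector minus control vector, x axis) of each measured member of the 12 lists that shifted by camera and of 4 neuronal lists, with the list's median as a black bar; colour shows which members passed an adjusted p of 0.05 over all genes. The median was 0.54 for NF-kB targets and -0.36 for G2/M genes, and lay between -0.05 and 0.04 in the 4 neuronal lists.

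Glioma and glial lists did not pass camera either. Of 22 astrocyte markers, 4 fell and 18 did not pass, and 6 fell over the list alone (median 0.02, mean -0.13, test direction downward, camera adjusted p = 0.454; by fry, also downward, adjusted p = 0.043). The members that fell were ID3 (-1.21), the gliogenic factor gene SOX9 (-1.01, and -0.51 with the mean of its probe sets), ALDOC (-0.82) and the glutamate transporter gene SLC1A3 (-0.41), which did not pass with the mean of its probe sets (-0.15, adjusted p = 0.303). Of 24 glioma stem cell genes KLF4 (-1.04) fell and 23 did not pass, and 4 rose and 2 fell over the list alone (camera adjusted p = 0.871). Among 23 mesenchymal glioblastoma genes CEBPB rose by 0.53, COL1A2 (-0.69) and CHI3L1 (-0.51) fell and 20 did not pass, and over the list alone 3 rose and 2 fell (camera adjusted p = 0.871). Of 19 proneural glioblastoma genes TCF4 (-0.58) fell and 18 did not pass, with the same count over the list alone (camera adjusted p = 0.989). With the replicate block SLC1A3, CEBPB, CHI3L1 and TCF4 did not pass (adjusted p from 0.0604 to 0.0755). Of the markers of other cell types, 0 passed the test over all genes or over the list alone, among 20 for microglia and macrophages, 19 for oligodendrocytes, 18 for endothelium, 19 for epithelium and 29 for skeletal muscle; by limma 3, 3, 3, 4 and 3 of them had an unadjusted p below 0.05.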

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

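The test of probe sets without a single gene name was chosen after the data were seen. Probe sets that the annotation gives no gene symbol or several symbols took no part in the comparisons of genes and entered only the fit over all probe sets. In the limma fit over all probe sets, 52 of them were higher with the NeuroD2 vector at an adjusted p below 0.05, 24 with no symbol and 28 with several. A further 37 with no symbol and 24 with several were lower. These are 2.47% of the 2473 probe sets with no symbol and 2.84% of the 1832 with several, against 2.90% of the 44988 with a single symbol. The largest rise was 1.95 on the log2 scale among those with several symbols and 1.40 among those with none. Their genes are not named here.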

How the results depend on the processing

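All alternatives were planned. None of them reversed the direction of a called result among NEUROD2, the other named genes and the gene lists, though genes picked on all 4 arrays could hardly reverse without 1 of them. The replicate block gave 335 changed genes, of which 327 were among the 864, and left the 12 lists as they were. Of 101 called genes among the named genes and list examples other than NEUROD2, 38 did not pass with it (adjusted p from 0.0502 to 0.0885). Same-numbered arrays correlated at 0.08 in their deviations, so with 2 pairs the numbers were taken as names, not as a pairing. An intensity trend gave 2056 changed genes, a filter to genes at or above the median level gave 2081 of 9066, and testing every probe set on its own, those without a single gene symbol included, gave 1416, with 173 past the size rule. With the trend TK1, RAB3B, ERO1A, E2F2, SREBF1, H4C8, SDHA, NDUFB6 and COX7A2, which did not pass in the report, passed (adjusted p from 0.0043 to 0.0460), all but NDUFB6 also under another setting. The filter tests fewer genes; the cause of the other changes was not tested. Quantile normalization (961), median centring (928), a robust prior (807) and the mean of probe sets (1187, sharing 666 of the 864) stayed within 1.5 times the main count. With 1 array left out, changed genes ranged from 0 to 66, genes past the size rule from 72 to 86, shifted lists from 11 to 13 and the NEUROD2 difference from 1.97 to 2.42. NEUROD2 no longer passed without control replicate 1 (adjusted p = 0.141) or control replicate 2 (0.147), and its adjusted p lay between 0.00014 and 0.0185 under the settings that kept all 4 arrays; the filter left it out, as its mean lies below the median level. Among calls without a NeuroD2 array, 61.4% (replicate 1 left out) and 56.1% (replicate 2 left out) were higher, against 38.0% of the 864. In simulations, genes changed by 1 were recovered at 32.6% (0 to 81% between draws) with 2 NeuroD2 arrays against 1 control array and at 35.6% (0 to 80%) with 1 NeuroD2 array against 2 control arrays, and 9.79% and 9.47% of the calls were false, against 4.69% for 2 against 2. These simulations gave both groups the same spread. The real control arrays differed more (median absolute difference 0.12) than the NeuroD2 arrays (0.07). With an estimated correlation, which rests on the 2 residual degrees of freedom, 0 lists passed camera (4 had an unadjusted p below 0.05), and with fry 16 did. Of the 12 lists, 7 passed under every setting that kept the preset correlation: NF-kB targets, G2/M, G1/S, cholesterol synthesis, immediate early genes, oxidative phosphorylation and interferon response. The 4 arrays split into 2 and 2 in only 3 ways, too few for a share below 0.05. The real split gave 864 genes in 1 of 3 splits and the highest of the others gave 0. The other splits mixed control and NeuroD2 arrays on each side. Any difference between the groups, technical ones included, then adds to the spread within sides and lowers those counts, so the contrast decides nothing. Background probe sets averaged 2.86 to 2.90 on single arrays at low GC content and 7.46 to 7.95 at high GC content. Probe sequences were not used here, so no gene was set against matching background. This limits differences at dim control levels, such as those of NEUROD2 (5.40), IL24 (5.69), CXCL5 (5.29), EDN1 (4.81), SERPINB4 (4.69), HSPA6 (4.38), EPHA5 (4.33) and CHGB (4.09).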

Other observations

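The tests of symbol families, of a difference of control replicate 1, of macrophage-type cells, of an interferon response and of the vector's insert were chosen after the results were seen. Interleukin and CXCL chemokine genes were more frequent among the risen genes than among all genes. Of 349 families of at least 8 genes whose symbols begin with the same letters, 2 held more risen genes than chance by a one-sided Fisher's exact test with Benjamini-Hochberg adjustment. The units of this test are genes, not cultures. In the family of symbols that begin with IL, 10 of 85 genes rose (adjusted p = 0.00057). Besides IL24, IL1B and IL36RN these were IL1A (1.57), IL6 (1.37), the interleukin-1 receptor gene IL1R1 (1.20), the receptor antagonist gene IL1RN (1.17), IL11 (0.94), IL36B (0.88) and IL12A (0.57). In the CXCL family, 5 of 14 rose (adjusted p = 0.00057), namely CXCL5, CXCL3 (1.58), CXCL2 (1.26), CXCL1 (1.15) and CXCL8 (1.09). The CXCL genes, IL1A, IL1B, IL6 and IL11 are also members of the NF-kB list, and the CXCL genes include close paralogs whose probe sets can share signal.

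Other lists did not pass camera but held large changes in single members. Of 26 matrix proteases 4 rose and 3 fell (median -0.01, mean 0.16, camera adjusted p = 0.795), with MMP1, MMP3 and ADAMTS5 (1.38) higher and the plasminogen activator gene PLAT (-0.94) lower. Of 26 p53 targets 1 rose and 6 fell (camera adjusted p = 0.0501), with TP53I3 (-0.88), SESN1 (-0.69) and TNFRSF10C (-0.68) lower and ZMAT3 (0.69) higher. Of 30 angiogenesis factors 3 rose and 3 fell (camera adjusted p = 0.080), with FGF2 (1.57), CXCL8 and EDN1 (0.69) higher and ANGPT1 (-0.81) lower. Of 20 heat shock genes HSPA6 rose by 1.51, from 4.38 on the control arrays (camera adjusted p = 0.080). The calls of these last 3 lists depended on the setting. The p53 targets passed without NeuroD2 replicate 1 (adjusted p = 0.025), with median centring (0.044), an intensity trend (0.048) and fry (0.037). Angiogenesis factors passed without NeuroD2 replicate 2 (adjusted p = 0.0498), with an intensity trend (0.048), the mean of probe sets (0.021) and fry (0.044). Heat shock genes passed without control replicate 2 (adjusted p = 0.043), with quantile normalization (0.048), an intensity trend (0.048) and fry (0.014). Of 13 hypoxia regulators EPAS1 (0.44) and CITED2 (0.43) rose (median -0.01, camera adjusted p = 0.249), and the list passed upward without control replicate 2 (median 0.14, adjusted p = 0.043) and among genes at or above the median level (median 0.16, adjusted p = 0.041). Tricarboxylic acid cycle genes (camera adjusted p = 0.099) passed downward with an intensity trend (0.048), the mean of probe sets (0.045) and fry (0.022), glycolysis genes (0.154) with an intensity trend (0.048) and apoptosis regulators (0.461) with fry (0.043). With an estimated correlation none of these lists passed. Of 23 NRF2 targets 4 rose and 3 fell (camera adjusted p = 0.454). AKR1B10 fell (-0.67, adjusted p = 0.014 by limma), also with the replicate block (adjusted p = 0.042). The close paralogs AKR1C2 (-0.93) and AKR1C3 (-0.54) fell while AKR1C1, named after its value was seen, rose by 0.42, on probe sets that can share signal. AKR1C2 (-0.25, adjusted p = 0.085) and AKR1C3 (-0.23, adjusted p = 0.134) did not pass with the mean of their probe sets. With the replicate block AKR1C2 (adjusted p = 0.0503), AKR1C3 (0.0693), ANGPT1 (0.0605), EDN1 (0.0699), EPAS1 (0.0694) and CITED2 (0.0709) did not pass. BMP2 rose by 2.39 while ID1, ID2 and ID3 and the inhibitory SMAD gene SMAD6 (-1.01) fell and SMAD7 (0.27) did not pass (adjusted p = 0.121), a set put together after the values were seen. Of the 44 lists, 32 did not pass, with adjusted p-values from 0.0501 to 0.989, and in 9 of these the median, the mean and the test differed in sign: hypoxia regulators, astrocyte markers, matrix proteases, neuronal markers, the proneural cascade, mesenchymal and proneural glioblastoma genes, calcium signalling and chromatin modifiers.

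In the rise of inflammatory NF-kB targets, against control replicate 2 alone the list's median difference was 0.50. Its ratio to the median against both controls had a 95% bootstrap interval of 0.864 to 1.21. The bootstrap resampled genes, so this interval gives the spread between genes and not between arrays. The rise was thus not limited to the comparison with control replicate 1, the array with dim poly-A spikes, though only 1 control array remained. The test was first run on the median itself, whose interval of 0.21 to 1.23 reached below the bound of 0.27 and left it undecided; the ratio, which compares the same genes, was taken after that was seen. Macrophage-type cells would bring their own abundant transcripts. The median of 20 microglia and macrophage markers had an upper 95% bootstrap limit of 0.12, below the bound of 0.27 set from the list's median. Of the 20, 0 are in another list, and the brightest, CD68, read 10.10 on the control and 10.17 on the NeuroD2 arrays. As 19 of the 20 lie below the median level of all genes, a small number of such cells could go unseen. Both groups were transfected, so only an unequal response to transfected DNA would show. A stronger response through interferon with the NeuroD2 vector would raise interferon genes, whose median was -0.11. A response without interferon was not tested and stays open. Still open are an effect of the NeuroD2 vector, which was not tested further, and a small number of macrophage-type cells. A technical difference between the arrays of the 2 groups, whose hybridisation spikes differed by 0.39 (0.22 against control replicate 2 alone), also stays open. So does a difference between the cultures or plasmid preparations of the 2 groups.

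The second pattern is the lower level of G2/M, G1/S and cholesterol synthesis genes. A normalization shift that depends on brightness would move other genes of the same level too, but the medians of the 3 lists stood at percentile 0 of 10000 random lists matched on mean level. Against control replicate 2 alone the median of the 84 measured genes was -0.31. Its ratio to the median against both controls had a bootstrap interval of 0.843 to 1.06. Genes were resampled here too, so the interval gives the spread between genes and not between arrays. The lower level was thus not limited to the comparison with control replicate 1, though only 1 control array remained. For the G2/M and G1/S genes, a candidate explanation is a lower share of dividing cells in the NeuroD2 cultures. Cell density and cell number were not used here, so this stays open. A direct effect of the vector stays open for all 3 lists. So does a technical difference between the groups' arrays, as for the hybridisation spikes (0.39, and 0.22 against control replicate 2 alone).

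The third pattern is the rise of NEUROD2 on a single probe set. Signal from NEUROD4, NEUROD6, NEUROG1, NEUROG2 or NEUROG3 could also appear on that gene's own probe sets. The highest upper 95% limit among the 6 probe sets of these 5 genes was 0.30, below the bound of 1.10 set from the NEUROD2 difference. This cannot exclude these genes, as NEUROD2's own other probe sets stayed level while its brightest rose. Relatives not analysed here, NEUROD1 among them, stay open as well. The wording of this explanation was narrowed to measured genes after the result was seen, with its bound unchanged. Probe sets outside the part of the gene carried by the vector could stay level, as the second-brightest did (-0.21); without the insert and the probe sequences this cannot be told apart from probe sets that respond poorly.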
